A study of Staphylococcus aureus with 6 samples.

How the data were processed

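The series measured transcript ratios in Staphylococcus aureus COL, a methicillin-resistant strain, after 15 min with a terpeneless, cold-pressed Valencia orange oil at 0.5 times its minimum inhibitory concentration, against cultures kept 15 min without the oil. Per the labels' protocols, cultures in tryptic soy broth were treated at an optical density of about 0.4, RNA was stabilised, cells were broken in Trizol, RNA was cleaned on columns and treated with DNase, and cDNA primed with random hexamers was coupled to Cy3 or Cy5. Each of 6 two-colour spotted arrays held oil-treated cDNA in one channel and untreated cDNA in the other. The arrays are numbered as 3 experiments of 2, array A with the oil-treated cDNA in Cy5 and array B with it in Cy3. The labels do not say that arrays A and B, or the 3 experiments, came from separate cultures, so p-values measure the spread between these 3 experiments, which may be partly technical. Array 1B carries one label that names its second channel as the control, against its treatment characteristic and the series' design. The treatment characteristic was used.

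Per the series' design text, the authors scanned the arrays on an Axon scanner, quantified spots with TIGR Spotfinder, subtracted the local background, normalized with LOWESS in TIGR MIDAS, discarded genes with fewer than 3 data points and tested with SAM. Versions of the quantification, normalization and SAM software are not given in the sources used here. The deposited array files hold, per spot and channel, the intensity minus local background and the background intensity itself, before LOWESS. Channel A is Cy3 and channel B is Cy5, per the labels. The authors' deposited value table holds 1 log2 ratio per element and array. Set against the array files it runs in the direction of oil over untreated on all 6 arrays, with Pearson correlations across elements of 0.94 to 0.96 and slopes of 0.86 to 0.89. Its column medians are -0.28, -0.20, -0.18, -0.23, -0.21 and -0.22 for arrays 1A, 1B, 2A, 2B, 3A and 3B, and its centring and its handling of repeat spots stay unknown.

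A spot listed under several locus tags was counted once, by its position. The grid held 12364 spots of 2963 elements (12236 spots on array 1B), and 4 spots per element was the usual number. An intensity of 0 marks a spot that was not found, so only spots with both intensities above 0 were used. These were 75.2% of spots on array 1A, 80.1% on 1B, 68.5% on 2A, 73.7% on 2B, 73.1% on 3A and 74.5% on 3B. The background-subtracted intensities were used as given, the log2 ratio of Cy5 over Cy3 was normalized within each array by global loess on mean log2 intensity (span 0.3, 4 iterations), and no scaling was applied between arrays. Ratios were turned to oil-treated over untreated, repeat spots were averaged per element, and arrays A and B were averaged per experiment, which cancels a dye effect where both were measured. Elements needed a ratio on at least 3 arrays and in at least 2 experiments, which left 2443, of which 66 were measured in 2 experiments only and 2146 on all 6 arrays. In at least 1 experiment 280 elements rested on a single dye orientation, where a dye effect is not cancelled. Of these 77 rose, 101 fell and 102 did not pass. The mean of the 3 experiments was tested against 0 with limma (lmFit and eBayes, two-sided, limma 3.58.1 in R 4.3.3, statmod 1.5.0), with Benjamini-Hochberg adjustment over all 2443 elements and a threshold of 0.05. Every adjusted p of a gene comes from this fit. The number of arrays limits the precision, and the median standard error of an element was 0.13 on the log2 scale. Changes are relative to the loess zero line of each array: an array ratio shows unequal change, and says nothing of a change shared by all transcripts. The sources used here gave no saturation marks, scan dates or slide batches.

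Elements carry the locus tag of strain COL and a product text from the array files. The gene lists (33), the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. List members were matched to locus tags by product text before any gene's ratio was looked at. The product text does not name vraS, vraT, vraX, walK and cwrA. Their tags come from general knowledge of strain COL, were not checked on a genome, and were written with the lists only for vraT, vraX and cwrA. No genome of strain COL was used, so no coordinates are given, and the table of another strain's genes was not used for names. Where several elements stand for a gene, the one with the highest mean signal is given. Lists were tested with limma's camera (preset inter-gene correlation 0.01, two-sided) over 2170 genes measured in all 3 experiments, with adjustment over the 30 lists that had at least 5 such members. The plan was to test lists over array elements. The test was run with 1 element per gene instead, so that genes with several elements did not count more than once. Camera was also run with an estimated correlation, and fry beside it. With 3 experiments camera has few degrees of freedom in that setting, so a miss there says little against a list. Counts and medians of a list cover all its measured members unless stated. Counts of list members past the threshold are given over all elements tested and adjusted over the list alone. The rule for named genes took the 15 largest rises and 15 largest falls past the threshold with the same sign in 3 experiments, up to 4 members per list with the smallest p, and 25 genes named in any case. Of these 25, cidA, hla and kdpA had no tested element. The rule gives more genes than the text can hold, and those named were picked from its pool after their values were seen. The prophage genes SACOL0318, SACOL0321, SACOL0325, SACOL0364, SACOL0370 and SACOL0388 lie outside the rule and were chosen after their values were seen. So do ruvA and umuC. The genes recA and lexA also lie outside it and were chosen after the prophage's values were seen but before their own were looked at.

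The dye effect was tested in the same way on 0.5 times the difference between arrays A and B of each experiment. The steps were tested on simulated spots built from the real signals with a dye trend and 200 changed elements among 2443. Of 50 elements changed by 0.5 on the log2 scale, 66% were recovered, and 100% of the 50 each at 1, 2 and 4 on that scale, with 6 false calls. All simulated elements shared the same noise level, and far fewer were changed than the 1948 that passed in the real data. These shares and false calls thus need not hold for the real calls. In a second simulation with all measured changes as the truth, the median error was 0.009 and the SD of the error 0.15. That truth already lay on the loess zero line, so it cannot show whether loess placed the zero rightly in the real data. A simulated list with a shift passed in camera and 0 of 20 random lists did. The simulated genes varied independently, while the estimated correlation reached 0.82 in the aspartate, lysine and threonine list. False passes of lists with correlated genes were not tested. Alternatives covered the normalization (median centring, print-tip loess, scaling between arrays), the background correction (normexp with an offset of 50), an offset of 50 on both channels, filters on dim and missing elements, the median of repeat spots, 6 arrays as replicates with and without a dye term or an experiment block, a SAM-type statistic with 64 sign flips, the authors' deposited table, each experiment or array left out, array 1B with its sign turned, a 2-fold minimum and another eBayes prior. The count of elements found in 1 condition only, the 32 sign patterns over the 6 arrays and the grouping of mobile elements and of neighbouring genes were added after seeing the data.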

Results

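The response of Staphylococcus aureus COL to an orange oil was read on 6 two-colour arrays, 2 of opposite dye orientation in each of 3 experiments. Between 2310 and 2513 array elements gave a ratio per array. The median background-subtracted intensity of the spots used ranged from 104737 to 124738.5 in Cy3 and from 54079 to 90781 in Cy5. Values are log2 ratios of oil-treated over untreated culture, given as mean ± SD of the 3 experiments. The adjusted p-values come from limma.

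The oil changed most of the measured transcriptome within 15 min. Of 2443 elements tested, 957 rose and 991 fell past an adjusted p of 0.05, and 495 did not pass. At least a 2-fold change was reached by 613 of the risers and 522 of the fallers. The strongest changes were rises. After loess 162 elements rose at least 8-fold and 108 at least 16-fold, while 21 fell at least 8-fold and 0 at least 16-fold. Under normexp some falls did pass 16-fold, among them SACOL0176 at -5.20, sceD at -4.99 and plsC at -4.03 on the log2 scale. The highest rise was then 6.50. The median of all elements was -0.06 after loess and 0.06 with each array only centred on its median. It was -0.24 in the authors' deposited table, a median shift of -0.26 per element, where 749 elements rose and 1081 fell, so small changes depend on where each scaling puts its zero. The size of strong changes depends on the processing too: of 100 genes checked, the fold of 36 moved by more than 1.5 times in that table, of 20 with print-tip loess, of 12 with normexp and of 5 with median centring.

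**Figure D1:**
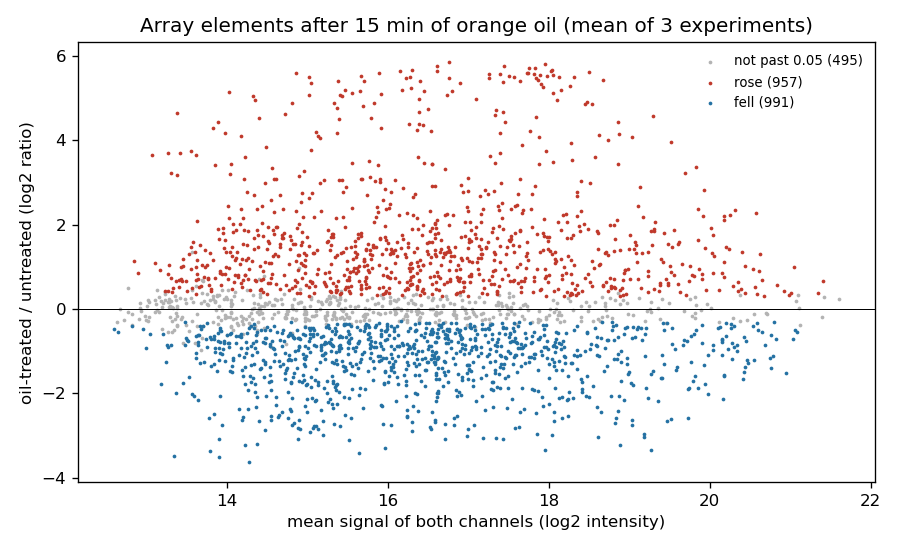
Each point is 1 of 2443 array elements, with the mean log2 intensity of both channels on the x axis and the log2 ratio of oil-treated over untreated culture (mean of 3 experiments) on the y axis. Red points rose (957), blue points fell (991) and grey points did not pass an adjusted p of 0.05; the rises reach 5.85 and the falls -3.63.

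Prophage L54a, an integrated phage of strain COL, supplied most of the strongest rises. Its Cro-related protein, SACOL0322, rose by 5.80 ± 0.17 (55.8-fold, adjusted p 8.5e-07, higher in 6 of 6 arrays; 4.67 in the authors' deposited table). The prophage was in no fixed list, and the groups and other prophage genes given here were chosen after their values were seen. Of the 50 elements with the highest ratios 38 lay in it, some of them elements of the same gene. All 56 elements from the Cro-related gene to the RinA regulator SACOL0364, which stand for 42 locus tags, rose with a median of 5.40 (42.3-fold). All 56 also rose in the authors' deposited table, with a median of 4.6. The antirepressor SACOL0325 rose by 4.92 ± 0.30 and SACOL0364 by 5.44 ± 0.11. The 4 elements before them rose less, with a median of 1.00. They include the integrase SACOL0318 at 1.06 ± 0.22 and the repressor SACOL0321 at 0.95 ± 0.36, whose rises did not pass in the authors' deposited table (0.38 and 0.29). The 3 elements of the terminase and protease genes rose, with a median of 3.27 (2.51 in the deposited values). None of the 16 elements from the capsid to the amidase gene rose. Their median was -0.16, 6 of them fell and 10 did not pass. With median centring 2 fell, and in the authors' deposited values 10 fell, where 1 of the 4 elements before the Cro-related gene rose. The major capsid gene SACOL0370 stood at -0.05 ± 0.29 (adjusted p 0.76; 0.069 with median centring and 0.12 with print-tip loess), and the holin SACOL0388, which opens the cell membrane for lysis, fell by 1.05 on the log2 scale, a fall that did not pass with median centring (-0.32). The holin element was measured only on the 3 arrays with the oil-treated cDNA in Cy3, so a dye effect on it is not cancelled.

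**Figure D2:**
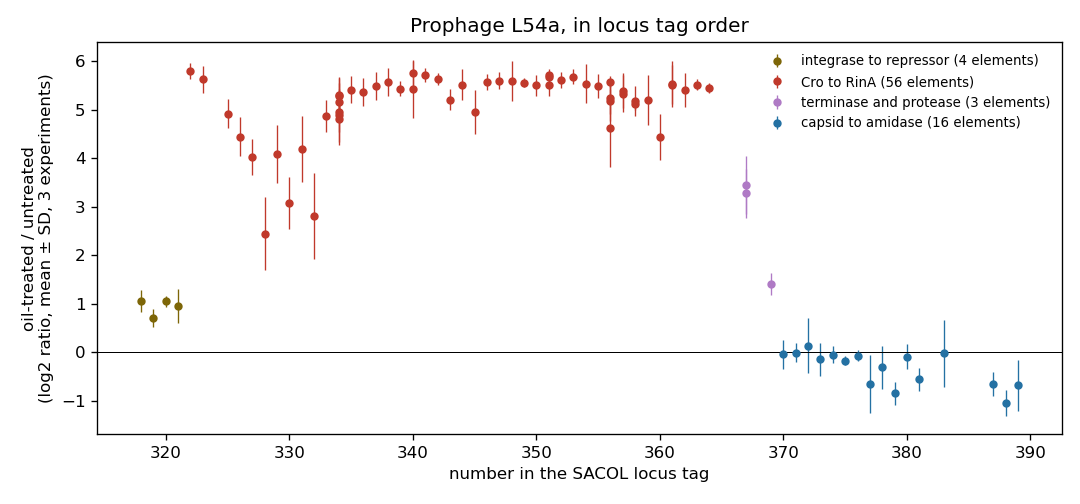
Log2 ratio of oil-treated over untreated culture (points, mean of 3 experiments; bars, SD) for the elements of prophage L54a, ordered on the x axis by the number in their locus tag. The 56 elements from the Cro-related protein to RinA have a median of 5.40, the 4 before them 1.00 and the 16 from capsid to amidase -0.16.

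Amino acid synthesis genes held many of the other strongest rises. All 9 measured genes of the aspartate, lysine and threonine list rose over all elements and adjusted over the list alone, with a median of 5.14, 4.29 in the authors' deposited table and 5.85 with normexp (camera adjusted p 6.2e-05; adjusted p = 0.44 with an estimated correlation). The aspartokinase gene lysC, the first step of the pathway, had the highest ratio of all elements at 5.85 ± 0.31 (57.6-fold, adjusted p 1.2e-06, higher in 6 of 6 arrays), with asd at 5.76 ± 0.44, dapA at 5.64 ± 0.30 and dapD at 5.48 ± 0.21. All 10 genes of the branched-chain list rose, also adjusted over the list alone, with a median of 5.08, 4.26 in the authors' deposited table and 6.01 with normexp (camera adjusted p 6.2e-05; adjusted p = 0.44 with an estimated correlation). Among them leuC rose by 5.59 ± 0.41, ilvD by 5.09 ± 0.18 and ilvA by 4.51 ± 0.28. Of the histidine genes 4 were measured, too few for a list test, and 3 rose: hisIE by 4.43 ± 0.26, hisA by 3.64 ± 0.70 and hisH by 3.35 ± 1.03. Their values under normexp were 5.79, 5.05 and 4.04, and hisA stood at 4.46 with median centring and 3.0 in the authors' deposited table. The elements of hisIE and hisH were measured on 5 arrays, so 1 experiment of each had a single dye orientation. Of 7 arginine genes 3 rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone (median 0.21, 0.82 with median centring, camera adjusted p 0.90). The median of the arginine genes in the list test, 0.06, was -0.27 without experiment 1.

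The cell wall stress stimulon, the genes S. aureus raises when cell wall synthesis is blocked, rose as a list. Of 16 members 12 rose and 4 fell, also when adjusted over the list alone, with a median of 1.17 (camera adjusted p 0.019; adjusted p = 0.44 with an estimated correlation). The highest were SACOL2571 (cwrA), at 5.47 ± 0.34 (44.3-fold, adjusted p 1.3e-06; 4.59 in the authors' deposited table), and SACOL0625 (vraX), at 4.57 ± 0.19 (23.7-fold, adjusted p 1.2e-06), both listed as hypothetical proteins, with the gene names in brackets not checked on a genome of strain COL. The genes of the VraSR regulator that controls the stimulon rose as well, the sensor kinase SACOL1943 (vraS, also not checked) by 2.73 ± 0.14 and vraR by 2.44 ± 0.11 (1.38 in the authors' deposited table). The glycosyltransferase gene sgtB rose by 1.43 ± 0.15 and murZ by 0.95 ± 0.06. The penicillin-binding protein gene pbp2 rose by 0.73 ± 0.13, lowest on array 1A at 0.37. It did not pass with print-tip loess (0.01) and had the opposite sign in the authors' deposited table (-0.28).

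Of 17 genes of murein hydrolases and their regulators 4 rose and 11 fell, also adjusted over the list alone, but the list did not pass (median -0.63, camera adjusted p 0.14). The lytic transglycosylase genes sceD and isaA stood at -3.50 ± 0.61 and -3.04 ± 0.50 (11.3-fold and 8.25-fold lower, adjusted p 2.6e-05 and 2.5e-05, each lower in 6 of 6 arrays). The value of sceD was -2.81 with print-tip loess and -4.99 with normexp. The antiholin-like lrgA stood at -2.37 ± 0.57, scdA at -2.62 ± 0.14 (-2.31 on array 1A, apart from the others) and lytM at -0.94 ± 0.36, all past the threshold, while the response regulator gene arlR rose by 2.23 ± 0.23. The major autolysin gene atl rose by 0.38 ± 0.09 (adjusted p 0.019). This small rise did not pass without experiment 2 (0.34) or 3 (0.37) or without array 1B (0.34) or 3A (0.28), and had the opposite sign with print-tip loess (-0.16) and in the authors' deposited table (-0.26), and the gene's other element stood at -0.14. The teichoic acid list fell (median -1.07, camera adjusted p 0.022; adjusted p = 0.44 with an estimated correlation), with 8 of 10 genes down and 1 up, also adjusted over the list alone. It was led by the D-alanylation genes dltA at -2.97 ± 0.27 and dltD at -2.74 ± 0.26. Of 25 peptidoglycan synthesis genes 7 rose and 15 fell, also adjusted over the list alone (median -0.50, -0.82 in the authors' deposited table, camera adjusted p 0.14). The methicillin resistance gene mecA fell by 1.89 on the log2 scale (3.71-fold, adjusted p 3.4e-05, lower in 6 of 6 arrays but by less on 1B, at -1.07; -0.98 with print-tip loess and -1.10 in the authors' deposited table), mraY by 1.62 and murB by 1.57.

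Heat shock and protein quality control genes rose as a list (13 of 19 up and 4 down, also adjusted over the list alone, median 1.69, 1.12 in the authors' deposited table, camera adjusted p 0.016; adjusted p = 0.44 with an estimated correlation). The disaggregase gene clpB rose by 3.76 ± 0.40 (13.6-fold), mcsB by 3.45 ± 0.35, clpC by 3.43 ± 0.28 (4.0 on array 3B, above the others) and the chaperone gene dnaK by 2.35 ± 0.05 (1.42 in the authors' deposited table, where clpC was at 2.56). Of 20 oxidative stress genes 6 rose and 8 fell, also adjusted over the list alone. Their median was 0.03 (-0.11 with median centring, 0.33 with print-tip loess and 0.19 in the authors' deposited table) and their mean -0.005, and the test's direction was up without passing (camera adjusted p 0.98). The catalase gene katA rose by 2.83 ± 0.14 and msrA2 by 1.47 ± 0.13, while the flavohaemoglobin gene hmp stood at -2.19 ± 0.24, past the threshold. Of 16 genes of the general stress factor sigma B and its regulon 10 rose and 5 fell, also adjusted over the list alone (median 0.55, camera adjusted p 0.16). The median of this list was 0.08 with print-tip loess and 0.06 in the authors' deposited table. The marker asp23 rose by 1.25 ± 0.16. The sigB gene rose by 0.72 ± 0.20, which did not pass with print-tip loess (0.04) or in the authors' deposited table (0.09). Of 12 potassium and osmolyte genes 9 rose and 2 fell (3 fell adjusted over the list alone), with a median of 1.31 that missed the threshold as a list (camera adjusted p 0.053) and passed in the authors' deposited table (0.88, adjusted p 0.028). The glycine betaine genes opuD2, betB and betA rose by 3.23 ± 0.11, 3.06 ± 0.12 and 2.29 ± 0.21, and proP rose by 1.78 ± 0.07. The value of betA was 1.60 with print-tip loess and 1.36 in the authors' deposited table.

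Fermentation and anaerobic genes had the lowest median of the lists tested. Of 19 measured 18 fell and 1 did not pass, also adjusted over the list alone, with a median of -2.45 (camera adjusted p 1.2e-05; adjusted p = 0.44 with an estimated correlation). The nitrite exporter gene narK fell by 3.35 on the log2 scale (10.2-fold), the lactate dehydrogenase gene ldh1 by 3.34 (10.1-fold), nirR by 3.05, adh1 by 2.74 and pflA by 2.57. With print-tip loess narK stood at -2.41 and ldh1 at -2.49. The lactate permease SACOL2363, in no list, fell by 3.22 (9.3-fold, adjusted p 7.6e-06; -2.14 with print-tip loess). Purine synthesis fell in 14 of 16 genes (median -1.76, -1.17 with median centring, camera adjusted p 0.0031) and pyrimidine synthesis in 10 of 10 (median -1.25, -0.68 with median centring, camera adjusted p 0.0081), also adjusted over each list alone. Both had an adjusted p = 0.44 with an estimated correlation. Examples were purK at -2.78 ± 0.51, purA at -2.53 ± 0.30 (-1.76 on array 1A, apart from the others), pyrH at -2.46 ± 0.16 and pyrD at -2.34 ± 0.36. Glycolysis fell in 10 of 12 genes (median -1.05, camera adjusted p 0.0058), among them gapA1 at -1.77 ± 0.15. The ATP synthase genes fell in 8 of 8 (median -0.97, -0.63 with print-tip loess, camera adjusted p 0.0091), among them atpA at -1.12 ± 0.10, though the list missed the threshold in the authors' deposited table (adjusted p 0.064). In both lists the counts were the same adjusted over the list alone, and the adjusted p = 0.44 with an estimated correlation. Sugar transport and use fell in 13 of 21 genes and rose in 4, also adjusted over the list alone, without passing as a list (median -0.73, camera adjusted p 0.089; 0.018 without experiment 2; the array medians stood apart on 2B, at -0.46). The glucose transporter gene ptsG fell by 2.95 and gntK stood at -2.88, with another gntK element, among the 15 largest falls, at -3.19. Of 15 tricarboxylic acid cycle genes 3 rose and 7 fell, also adjusted over the list alone (median -0.18, -0.33 with median centring and -0.56 in the authors' deposited table, camera adjusted p 0.35), with citrate synthase gltA up by 1.19 ± 0.13 and pckA at -1.27 ± 0.32.

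All 16 capsule genes rose, with a median of 1.65 (camera adjusted p 6.2e-05), among them cap5N by 2.32 ± 0.21 and cap5K by 2.11 ± 0.06. All 7 urease genes rose, with a median of 1.31 (camera adjusted p 0.0091), led by ureC at 1.77 ± 0.23. In both lists the counts were the same adjusted over the list alone, and the adjusted p = 0.44 with an estimated correlation. Of 13 surface adhesin genes 8 rose and 2 fell, also adjusted over the list alone (median 0.72, 0.33 with print-tip loess and 0.16 in the authors' deposited table, camera adjusted p 0.16). The risers include sdrC (SACOL0608) at 0.87, whose elements passed in opposite directions. The fibronectin-binding protein gene fnbA rose by 4.06 ± 0.04 (16.7-fold; 2.92 with print-tip loess and 2.67 in the authors' deposited table) and clfA by 1.45 ± 0.40, while the protein A gene spa fell by 2.12. Of 8 toxin and exoenzyme genes 2 rose and 1 fell, also adjusted over the list alone. Their median was 0.08, against 1.09 with median centring, 0.60 with print-tip loess and 0.52 in the authors' deposited table. The members in the list test had a median of -0.06 and a mean of 0.37, and the test's direction was up without passing (camera adjusted p 0.77). On array 3A the list's median stood apart, at 1.17. The enterotoxin B gene seb rose by 2.94 ± 0.05 (1.93 in the authors' deposited table). Its locus tag, SACOL0907, follows SACOL0906 of a phage terminase family protein, whose elements rose by 3.32 and 2.44. Whether the rise of seb belongs to the toxin genes or to that neighbourhood was not tested. Of 17 virulence regulators 9 rose and 5 fell, also adjusted over the list alone (median 0.34, 0.19 with print-tip loess and 0.05 in the authors' deposited table, camera adjusted p 0.33). The regulator gene sarA rose by 2.73 ± 0.16 and agrA by 0.65 ± 0.15, which did not pass in the authors' deposited table (0.19). The genes saeR and srrA fell by 1.17 and 2.55.

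Of 20 aminoacyl-tRNA synthetase genes 13 fell and 1 rose, also adjusted over the list alone (median -0.87, camera adjusted p 0.0086; adjusted p = 0.44 with an estimated correlation), with serS at -2.84 ± 0.30. Of 58 ribosomal protein genes 14 rose and 27 fell (26 fell adjusted over the list alone), without passing as a list (median -0.30, camera adjusted p 0.14; median -0.43 and adjusted p 0.013 with median centring; median -0.19 with print-tip loess; array median 0.03 on 3B, above the others). The gene for L33 stood at 1.55 ± 0.17 (0.78 with print-tip loess and 0.65 in the authors' deposited table). That for S20 stood at -1.58 ± 0.17, but had the opposite sign with print-tip loess (0.15) and did not pass in the authors' deposited table (-0.08). Cell division fell in 8 of 12 genes and rose in 2 (median -0.58, camera adjusted p 0.057; 0.032 with median centring, 0.028 in the authors' deposited table and 0.042 without experiment 3), with smc at -2.25 ± 0.02, ftsL at -2.08 ± 0.25, ezrA at -1.87 ± 0.21 and ftsZ at -0.97 ± 0.11, which did not pass with print-tip loess (-0.26). Fatty acid and phospholipid synthesis fell in 11 of 20 genes and rose in 2 (median -0.50, camera adjusted p 0.057; 0.021 with median centring, 0.022 in the authors' deposited table, where the median was -0.87, and 0.042 without experiment 3), with the acyltransferase gene plsC at -3.40 ± 0.39. The mevalonate pathway fell in 7 of 10 genes and rose in 2 (median -1.10, camera adjusted p 0.14), with mvaS at -1.66 ± 0.19 (-2.25 on array 3B, apart from the others) and mvaD at 1.68 ± 0.11. In these last 3 lists the counts were the same adjusted over the list alone. Of 12 iron acquisition genes 2 rose and 6 fell (median -0.85, -0.39 with median centring, camera adjusted p 0.16), with sirC up by 3.37 ± 0.04 and htsA at -2.58 ± 0.29. Of 21 DNA repair genes 7 rose and 9 fell (median -0.02, 0.33 with median centring, 0.02 with print-tip loess and -0.27 in the authors' deposited table, camera adjusted p 0.85), with the polymerase gene dinB up by 1.81 ± 0.11 (0.74 in the authors' deposited table), ruvB up by 1.22 ± 0.13 and recN at -2.56 ± 0.33 (-1.76 on array 1B, apart from the others). Both sets of counts were the same adjusted over the list alone. Of 3 measured efflux and peptide resistance genes, too few for a list test, 2 rose and 1 fell, with norA at 1.73 ± 0.16 and mprF at -1.16 ± 0.18. The other riser, emrB (SACOL2347), stood at 0.58, but its elements passed in opposite directions. The list of genes that strain COL lacks had 0 measured members.

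**Figure D3:**
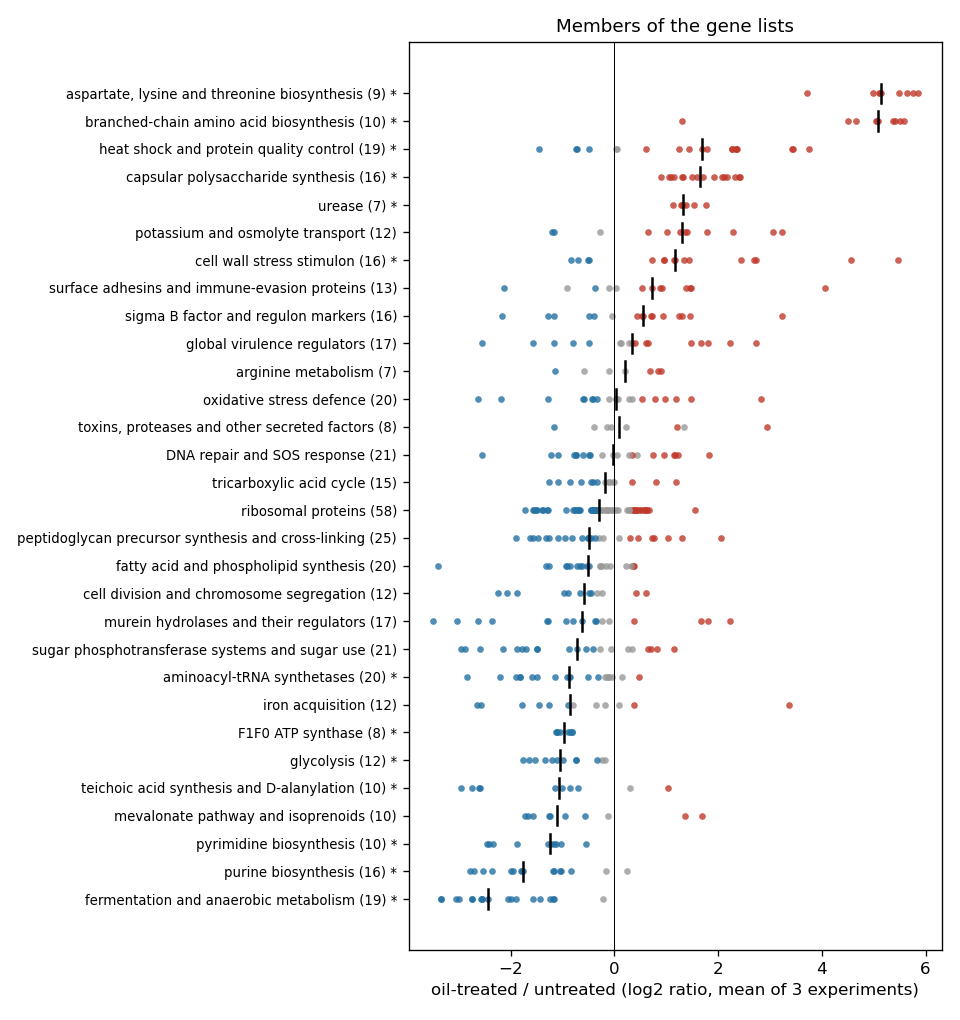
Each row is a gene list with its number of measured genes, and each point a gene placed by its log2 ratio of oil-treated over untreated culture (mean of 3 experiments); red points rose, blue points fell and grey points did not pass an adjusted p of 0.05. Black bars mark list medians and asterisks the 13 lists past 0.05 in camera, from aspartate, lysine and threonine synthesis at 5.14 to fermentation at -2.45.

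Of the 30 lists, 13 passed in camera with the preset correlation, 6 higher and 7 lower than other genes. With an estimated correlation 0 lists passed. The ATP synthase and aminoacyl-tRNA synthetase lists missed too, though their estimated correlations, 0.0036 and -0.011, lay below the preset 0.01. Their loss is thus not due to a higher correlation. Estimated from 3 experiments, this setting could hardly pass any list, so it decides nothing about single lists. In the other passing lists the estimate lay above the preset, from 0.065 for teichoic acid to 0.82 for aspartate, lysine and threonine. Among them were the branched-chain list at 0.57, urease at 0.58 and capsule at 0.53. For lists of genes that vary together, the camera p-values with the preset correlation may be too small. In fry, which does not compare a list with other genes, 26 lists moved one way on balance.

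Other strong single changes lay outside the lists. Among the 15 largest rises were the hypothetical proteins SACOL0047 at 5.64 ± 0.16 and SACOL0063 at 5.60 ± 0.34. The largest fall was that of the hypothetical protein SACOL0176, at -3.63 ± 0.56 (12.4-fold, adjusted p 1.8e-05, lower in 6 of 6 arrays and lowest on 3A at -4.93; -5.20 with normexp).

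Across elements, which are not independent replicates, Pearson correlations between experiments were 0.97 for each pair and Spearman correlations 0.95 to 0.96. Between single arrays Pearson correlations ran from 0.92 to 0.98, and those of array 1B with the other arrays from 0.92 to 0.97, all positive with its channels taken from the treatment characteristic. The dye effect was small beside that of the oil: the dye part of the ratio had an SD over elements of 0.21 against 1.68 for the oil. In limma 0 of 2324 elements passed, and 458 had an unadjusted p below 0.05, more than the share of 0.05 that chance gives. The largest dye part was 1.21. The lack of calls with 3 experiments thus does not show that elements were free of a dye effect.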

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

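The 6 arrays were searched for single values far from the other 5, and 11 of 133 values met the Dixon criterion where chance alone gives 6.65. None was weighed further. For pbp2 array 1A gave 0.37, against 0.73 to 0.85 on the others. For clpC array 3B gave 4.0, against 3.16 to 3.47. For mecA array 1B gave -1.07, against -2.23 to -1.84. For purA array 1A gave -1.76, against -2.79 to -2.61. For recN array 1B gave -1.76, against -2.87 to -2.53. For mvaS array 3B gave -2.25, against -1.61 to -1.48. For SACOL0176 array 3A gave -4.93, against -3.67 to -3.02. For scdA array 1A gave -2.31, against -2.78 to -2.61. The median of the ribosomal protein list was 0.030 on array 3B, against -0.32 to -0.20. The median of the sugar transport list was -0.46 on array 2B, against -0.84 to -0.73. The median of the toxin list was 1.17 on array 3A, against -0.27 to 0.23.

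Elements seen in 1 condition only lay outside the test. On all 6 arrays 7 elements had a signal in the oil-treated channel and none in the untreated channel, and 0 had the opposite. Against the lowest signals found, these 7 were at least 6.39-fold to at least 13.1-fold higher with the oil. They include a GntR family regulator, a formate dehydrogenase and a protein similar to cystathionine gamma-synthase. In all, 520 elements were not tested. Among them 308 had no signal in the untreated channel on any array and 70 none in the oil-treated channel, with 67 in both counts. The need for a signal in both channels thus left out more elements seen only with the oil than seen only without it.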

How the results depend on the processing

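Of 2443 tested elements 1948 passed, and under the other normalizations, background corrections, filters, replicate units, tests and priors the number was within 1.5 times of that, except for the alternatives given here. With array 1B turned, as one of its labels would have it, 3 elements passed (3 rose and 0 fell), the lowest correlation between experiments was 0.195 and lexA stood at -0.069. With a 2-fold minimum 1135 passed (613 rose and 522 fell), by construction. Without an experiment 1813 to 1836 elements passed, and without an array 1825 to 1966. In the authors' deposited values 1830 elements passed, 1620 of them also in the loess fit, 1607 with the same sign and 13 with the opposite sign. For the 100 genes checked, leaving out the setting with array 1B turned, 2436 of 2473 values kept direction and side of the threshold, 24 lost the call and 13 changed sign. The fold of 50 of these genes moved by more than 1.5 times in at least 1 setting. Most of the genes were picked for a large change or a small p, and some settings can hardly move a call. The share kept thus overstates the stability of all calls. Over all elements, 1658 of 1948 kept call and sign with print-tip loess and 1607 in the deposited values. With median centring SACOL0370 was 0.069, lexA -0.12 and the oxidative stress list -0.11. With print-tip loess atl was -0.16, S20 0.15 and SACOL0370 0.12. In the deposited table pbp2 was -0.28, atl -0.26 and lexA -0.15. Without 1 experiment or array SACOL0370 ranged from -0.16 to 0.11 and lexA from -0.11 to 0.20. Without 1 experiment the arginine list ranged from -0.27 to 0.34 and the oxidative stress list from -0.087 to 0.080. For these the cause was not tested. The sign of the DNA repair list's median also turned with the scaling, from -0.27 in the deposited values to 0.33 with median centring, and the toxin list's median lay between 0.08 and 1.09. Of 30 lists 13 passed, 16 with median centring and 15 in the deposited table. In fry, which asks another question, 26 passed. The count was 0 with an estimated correlation, a setting that could hardly pass any list with so few experiments. The lowest correlation between experiments was 0.966, 0.961 with median centring and 0.953 in the deposited table; the cause was not tested. The dye effect had 0 elements past in limma under loess and median centring, with 458 and 506 at an unadjusted p below 0.05. Matching average intensities between arrays cannot move ratios, so that setting says nothing on stability, and the offset of 50 is small beside the signals. Elements without enough signals in both channels could not be tested: 520 had too few ratios.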

Other observations

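Several blocks of neighbouring genes outside the fixed lists rose strongly, and these groups were chosen after their values were seen. All 8 elements of the Mnh sodium/proton antiporter genes SACOL0679 to SACOL0686 rose, with a median of 4.10 and a range of 3.64 to 4.24. A first grouping by product text also took antiporters elsewhere and was replaced by this tag range. Of all 18 tested elements whose text names an antiporter, 15 rose, 2 fell and 1 did not pass, from -0.54 to 4.24. The 6 of these from SACOL0949 to SACOL0955 rose by 0.40 to 1.06. All 7 elements from SACOL2588 to SACOL2594, which include a TetR family regulator and an oxidoreductase, rose with a median of 4.66. Of 9 elements whose text names a pathogenicity island 7 rose and 1 fell, with a median of 4.11 and a range of -0.91 to 4.99. Neighbouring locus tags had similar ratios (Pearson 0.637 over 2225 pairs, 0.562 without prophage L54a, highest of 1000 shuffled orders 0.0666), a correlation across genes, which are not independent replicates.

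Of 184 genes with several elements 4 had elements that passed in opposite directions: SACOL0272, SACOL0608, SACOL1041 and SACOL2347. The 61 elements that rose at least 32-fold had an SD of the log2 ratio of 0.21 and an SD of the oil-treated log2 signal of 1.18. These elements were picked by their ratio, which narrows the first SD but bounds the ratio only from below. Whether an upper limit of the measurable ratio held the strongest rises down was not tested. Nothing is concluded from the 2 values, and the largest folds may be too small. The highest ratio of any element was 5.85 after loess, for lysC (6.08 with normexp), and 6.50 with normexp, for an element of dapB (5.14 after loess).

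Of the tests that follow, that of carried-over phage DNA or a lost prophage and that of the normalization were chosen only after the result was seen, and the sign patterns over 6 arrays were added after seeing the data. The tests on recA and lexA and on the ribosomal protein list were prompted by the prophage and amino acid rises, after these were seen, and were set down before the values they rest on were looked at. The elements of prophage L54a from the Cro-related protein to RinA rose together, by a median of 5.40 (4.6 in the authors' deposited table). Phage DNA in the RNA would raise the capsid-to-amidase elements alike, but their median was -0.16, which argues against it. An untreated culture without the prophage would raise them only if the oil-treated culture transcribed them, so their median cannot decide on that. It would also raise the 4 elements before the Cro-related gene strongly. Their median was 1.00, at mean log2 signals of 14.2 to 19.1, which argues against a missing prophage. These 4 elements were taken up after their values were seen. A response to DNA damage would raise recA and lexA: recA rose by 0.96 ± 0.08 (adjusted p 2.8e-04; 0.28 and not past in the authors' deposited table), while lexA stood at 0.045 ± 0.22 (95% interval -0.27 to 0.36, adjusted p 0.76), and the DNA repair list did not pass (camera adjusted p 0.85), with a median of -0.02 whose sign depends on the scaling (0.33 with median centring, -0.27 in the authors' deposited table), so the list decides nothing. The rule set down beforehand took a missed threshold of either gene as evidence against it, which was wrong: a missed threshold does not show that lexA did not change, and its interval leaves room for a rise of up to 0.36. Other repair genes, looked at after their values were seen, moved apart: dinB rose by 1.81, ruvB by 1.22 ± 0.13, ruvA by 1.17 ± 0.14 and umuC by 1.15 ± 0.21 (4 arrays; 2.00 with median centring, 0.07 and not past in the authors' deposited table), while recN fell by 2.56. An SOS response thus cannot be told apart from its absence. Other routes of prophage induction were not tested.

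The branched-chain and aspartate-family genes rose together. The loess step as the whole cause is argued against by their median of 5.38 with each array only centred on its median, against 5.12 after loess. The size still depends on the processing, with a median of 4.29 in the authors' deposited table and 5.97 with normexp. A stringent-type response to amino acid shortage would lower the ribosomal protein list, and its median was -0.30 with a camera adjusted p of 0.14 (0.013 with median centring), so whether it took place cannot be told apart from its absence: the call depends on the scaling. No amino acid levels were measured, and other biological explanations were not tested.

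The number of elements past the threshold was set against other patterns of signs. Over the 3 experiments, 1 of 4 patterns, the real one, gave as many, with 1948 elements against a highest other of 0, but 4 patterns are too few for a share below 0.05. Over 6 arrays taken as separate replicates, 1 of 32 patterns, the real one, gave as many, with 1957 elements against a highest other of 17. Chance is excluded there only if the arrays are independent, which the labels do not state. The pattern of the dyes gave 0 elements in limma.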
